A study of Mus musculus with 12 samples.

How the data were processed

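Bulk RNA-seq of mouse kidney was available for 12 libraries in 3 groups of 4: control, chronic kidney disease (CKD) induced by adenine in the diet, and the same adenine model with colchicine at 0.3 mg/kg per day by intraperitoneal injection. Groups and replicate numbers were taken from the sample titles. The labels place every library in batch 1. They give 2% adenine for the 4 CKD libraries but 2, 3, 4 and 5% for the 4 colchicine libraries, while the design text describes one adenine model. The groups were kept as titled, and the labelled percentages were used only in alternatives and in a test of a slope. The design text calls the libraries biological replicates without naming the animals, so p-values measure the spread between these samples.

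RNA was isolated with RNAiso Plus reagent and libraries were made with a CORALL kit, per the labels' protocols. Per the submitters' processing notes, fastp, STAR and Salmon were used with the GRCm39 build; versions, annotation and settings are not given in the sources used here. The deposited values are one column per library of gene-level values in whole numbers, taken here as the authors' estimated counts (expected counts) rounded to whole numbers. The 28 values of 1000000 or more were all multiples of 10, so the largest counts carry rounding. No further rounding was needed. The files list 40213 gene symbols, of which 36900 were found in a RefSeq gene table of the GRCm38 build. That table was used only for symbols and gene classes, and no coordinates are given because the builds differ. Whether molecular identifiers were used in counting is not given in the sources used here, so counting intervals and floors cover counting error only.

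Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 17841, and libraries were scaled by TMM (trimmed mean of M-values). A robust quasi-likelihood model with 3 group means was fitted to all 12 libraries, so that the groups share one estimate of the spread. Each comparison was tested with a two-sided quasi-likelihood F test and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p below 0.05. CPM values are TMM-scaled counts per 1000000, given as mean ± SD over the 4 libraries of a group. Log2 fold changes are given with their standard error (SE). Principal components, list scores and set tests used log2 CPM with a prior count of 2.

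The comparisons and their tests, the gene lists, the rule for the genes named and the first set of alternatives were fixed before the data were examined. The 34 gene lists stand for nephron segments, other kidney and immune cell types, injury, fibrosis, metabolism, cell division, stress responses, and markers of other tissues or RNA quality. Of the listed symbols, 13 were matched under another name and 3 were not found. Lists were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 34 lists. Camera with an estimated correlation, fry, and an exact two-sided permutation test of the list score stood beside it. The score is the mean log2 CPM over the list, and 4 libraries against 4 give 70 arrangements and a smallest exact p of 0.0286. A further 7 lists were built after the leading genes had been seen. They are reported only among the other observations and are not independent evidence.

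The rule for the genes named takes the 8 highest and 8 lowest log2 fold changes among called genes whose groups do not overlap and whose mean count is 50 or more, leaving out predicted genes, immune receptor segments and pseudogenes. For colchicine against control it takes 4 each way. To these it adds the 2 members of each list with the smallest p, of which the text gives examples, and 22 genes of kidney injury, fibrosis, inflammation, tubulin and purine handling reported whatever their result. Genes named from the 7 later lists were chosen after their values were seen.

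The first set of alternatives comprised DESeq2 1.42.0, limma-voom, other scaling factors, other low-count filters, a 2-fold threshold, a fit of only the 8 libraries compared, the replicate number as a block, the labelled adenine percentage, and leaving out each library in turn. Scaling by library totals only, leaving out mitochondrial transcripts, and camera without colchicine replicate 1 were added after seeing the data. Where every library of a group was at 0, folds were computed against a floor of 3 counts over the group. With 1 to 3 counts in a group, the ratio is given with its 95% exact binomial interval.

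The models were tested on simulated counts with 200 changed genes among 17841. For colchicine against CKD, 41.5% of genes changed 1.5-fold, 72.5% of those changed 2-fold and 90.5% of those changed 4-fold were recovered. For CKD against control the shares were 42.5, 68 and 88.5%, and for colchicine against control 41, 67.5 and 92.5%. The real comparisons called far more than 200 genes, and the adjusted threshold depends on that number, so these shares need not hold for them. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.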

Results

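Gene expression was measured in kidneys of C57BL/6 mice in 3 groups of 4 libraries: control, adenine-induced CKD, and adenine-induced CKD with colchicine. Adenine in the diet is a model of crystal-induced tubular injury, and colchicine is an anti-inflammatory alkaloid that binds tubulin. Library totals, in units of 1000000 counts (M), ranged from 22.2 to 38.3 M. They averaged 27.6 ± 3.86 M in control, 24.8 ± 2.86 M in CKD and 30.8 ± 6.08 M with colchicine (SD, n = 4). Mitochondrially encoded transcripts took 43.6 ± 2.19% of the counts in control, 17.0 ± 0.263% in CKD and 17.8 ± 3.18% with colchicine. The share was lower in CKD than in control (exact permutation p = 0.0286), and no difference between colchicine and CKD was detected (exact permutation p = 0.714). That group mean covers a spread, with 14.6, 16.1, 18.9 and 21.8% in colchicine replicates 1, 2, 3 and 4, labelled 2, 3, 4 and 5% adenine. The CKD libraries lay between 16.7 and 17.3%. Whether the share follows the labels was not tested. The first principal component held 78.7% of the variance and separated control from both adenine groups. The colchicine libraries lay at 72.0 ± 6.37 and the CKD libraries at 58.5 ± 3.08 on it, so the colchicine group lay farther from control (exact permutation p = 0.0286). Colchicine replicate 1, which the labels give 2% adenine as in CKD, lay at 73.1, and replicates 2, 3 and 4, labelled 3, 4 and 5%, lay at 79.8, 70.8 and 64.4.

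**Figure D1:**
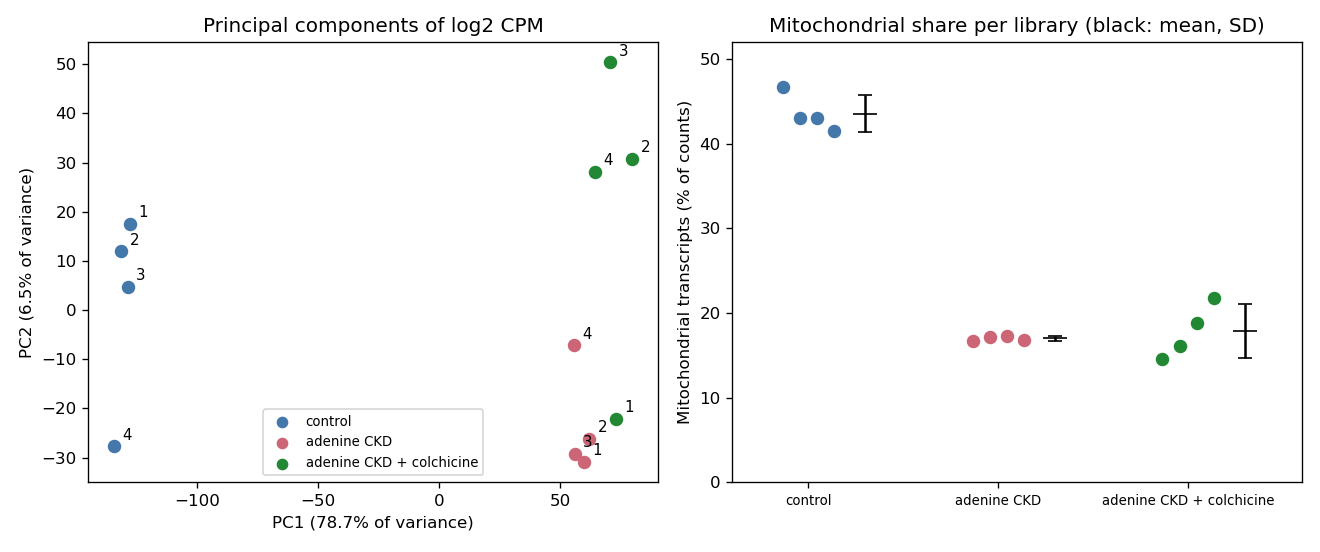
Each point is 1 library, numbered by replicate on the left, where the axes are principal components of log2 CPM (78.7% and 6.54% of the variance). On the right, the y axis is the percentage of counts from mitochondrially encoded transcripts, with the mean and SD in black, and the control libraries lie between 41.5 and 46.7% and the other 8 between 14.6 and 21.8%.

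The comparison of CKD with control asks what adenine feeding changed in the kidney. Tubular injury markers rose, including Lcn2 (lipocalin 2), from 5.08 ± 1.92 to 738 ± 37.8 CPM, and Havcr1 (kidney injury molecule 1), from 1.57 ± 0.289 to 188 ± 20.7 CPM (SD, n = 4). The phosphate transporter Slc34a1 of the proximal tubule fell from 4707 ± 143 to 293 ± 38.8 CPM. By edgeR's quasi-likelihood test at an adjusted p below 0.05, 6076 genes rose and 5952 fell, which is 67.4% of the 17841 tested. Of these, 3329 rose and 2739 fell by 2-fold or more.

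The genes with the largest increases under the naming rule include secreted and myeloid proteins. Il36a, an interleukin 1 family cytokine, was at least 171-fold higher against the floor, since the control libraries held no count. The cornified envelope gene Sprr2f, Cd300ld5 and the myeloid receptor Trem1 were likewise at least 163-fold, 95.0-fold and 83.0-fold higher. The metalloprotease Mmp7 rose 1327-fold and the transmembrane glycoprotein gene Gpnmb 359.7-fold. Without control replicate 1 the log2 fold change of Mmp7 was 11.22, against 10.37. Clca3b and the chemokine Ccl20 each had 1 control count, with ratios of 446 (interval 79.7 to 17619) and 409.6 (73.3 to 16201). That count lay in control replicate 2 for Clca3b and in control replicate 3 for Ccl20, so without that library the control held none. The genes with the largest decreases were mostly transporters and enzymes. The organic anion transporter Slco1a1 was 3347 times lower, Slc22a7 871 times, Cyp2d12 810.0 times, Slc22a28 641 times, the protease inhibitor Pzp 416 times, the distal tubule gene Pvalb 413 times, Slc22a30 349.6 times and Acsm3 262 times. Slc22a28, Slc22a30 and Cyp2d12 belong to families of similar genes, so their shares of common reads are uncertain.

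Among nephron lists, all 20 proximal tubule genes fell, with the peptidase gene Ggt1 13.1 times lower (camera adjusted p = 0.142 with an estimated correlation). All 20 injured tubule genes rose, with the hyaluronan receptor Cd44 35.6-fold and the adhesion molecule Vcam1 23.2-fold higher, and this list held with an estimated correlation (camera adjusted p = 0.0498). Of 15 genes of the loop of Henle and distal convoluted tubule, 12 fell and 2 rose, with Ppp1r1a at -2.67 ± 0.12 (log2, SE), while under library totals only 7 rose and 5 fell (camera adjusted p = 0.142 with an estimated correlation). Umod, the uromodulin gene of the loop, did not pass, at -0.24 ± 0.14 (edgeR adjusted p = 0.149), and stood at 0.76 under library totals only. Of 15 collecting duct genes, 13 fell and 1 rose, including the water channel Aqp3 at -2.82 ± 0.12 and the anion exchanger Slc4a1 at -4.46 ± 0.20, while under library totals only 4 rose and 9 fell, and under TMM this list was called with an estimated correlation too (camera adjusted p = 0.0498). Slc4a1 is also a red cell gene, and all 6 measured erythrocyte genes fell (camera adjusted p = 0.329 with an estimated correlation). Of 12 podocyte genes, 6 rose and 4 fell, while under library totals only 10 rose and 0 fell, and this list was not called. Of 12 endothelial genes, 10 fell, with the VEGF receptor Kdr at -1.40 ± 0.09, while under library totals only 10 rose and 1 fell (camera adjusted p = 0.142 with an estimated correlation).

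Camera at the preset correlation called most fibrosis and inflammation lists higher. All 20 fibroblast and matrix genes were higher, with the gelatinase Mmp2 23.7-fold, collagen Col1a1 13.4-fold and smooth muscle actin Acta2 2.12-fold, and fibronectin Fn1 by 4.32 ± 0.17 on the log2 scale (camera adjusted p = 0.0921 with an estimated correlation). Of 18 genes of TGF-beta signalling, 15 rose and 2 fell, with Tgfb1 at 2.00 ± 0.07 and Bmp7, which opposes it, at -1.86 ± 0.07 (camera adjusted p = 0.293 with an estimated correlation). All 16 macrophage genes rose, with the endotoxin receptor Cd14 at 4.21 ± 0.12 and the complement component C1qb at 3.81 ± 0.11 (camera adjusted p = 0.119 with an estimated correlation). Of 12 measured T and NK cell genes, 10 rose, with the interleukin 7 receptor Il7r at 5.82 ± 0.23 and Cd4 at 3.02 ± 0.20 (camera adjusted p = 0.170 with an estimated correlation). Of 6 measured B and plasma cell genes, 2 rose and 1 fell, and this list was not called. All 10 measured neutrophil genes rose, with the alarmin S100a8 34.1-fold and the growth factor receptor Csf3r 26.2-fold higher (camera adjusted p = 0.142 with an estimated correlation). Of 15 inflammasome and interleukin 1 genes, 12 rose and 2 fell, with the receptor antagonist Il1rn at 7.72 ± 0.19, the cytokine Il1b at 4.26 ± 0.32, the sensor Nlrp3 at 3.35 ± 0.26 and the caspases Casp4 at 3.52 ± 0.10 and Casp1 at 2.41 ± 0.15 (camera adjusted p = 0.0666 with an estimated correlation). Of 22 cytokine and chemokine genes, 20 rose and 1 fell, with the monocyte chemokine Ccl2 17.5-fold, the TNF receptor Tnfrsf1b 13.1-fold and the adhesion molecule Icam1 5.02-fold higher, and this list held with an estimated correlation (camera adjusted p = 0.0498). Of 13 complement genes, 11 rose and 2 fell, with the central component C3 71.8-fold higher, and this list also held (camera adjusted p = 0.0498). Of 15 interferon response genes, 11 rose and 1 fell, with the antiviral genes Mx1 at 2.79 ± 0.27 and Oasl2 at 1.68 ± 0.14 (camera adjusted p = 0.574 with an estimated correlation). The osteopontin gene Spp1, of the injured tubule list, rose 24.7-fold.

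Camera at the preset correlation called lists of cell division higher and of metabolism lower. All 20 mitosis genes rose, with the topoisomerase Top2a at 2.37 ± 0.24 and the proliferation marker Mki67 at 2.12 ± 0.22 (camera adjusted p = 0.319 with an estimated correlation). Of 18 DNA replication genes, 16 rose, with the helicase gene Mcm3 at 1.55 ± 0.12 (camera adjusted p = 0.347 with an estimated correlation). Of 15 p53 targets, 10 rose and 1 fell, with the cell cycle inhibitor Cdkn1a at 2.85 ± 0.19 and Phlda3 at 1.92 ± 0.14 (camera adjusted p = 0.329 with an estimated correlation). Of 12 tubulin genes, 9 rose and 2 fell, with Tubb2b at 2.82 ± 0.09, Tuba1a at 2.24 ± 0.10, Tubb5 at 2.14 ± 0.08 and Tubb2a at 1.23 ± 0.12 (camera adjusted p = 0.170 with an estimated correlation). Of 20 fatty acid oxidation genes, 19 fell, with the dehydrogenase Acadm 9.95 times lower, while under library totals only 1 rose and 13 fell (camera adjusted p = 0.126 with an estimated correlation). All 20 nuclear oxidative phosphorylation genes fell, with the complex II gene Sdhb 3.68 times lower (camera adjusted p = 0.142 with an estimated correlation). All 9 mitochondrially encoded transcripts fell, with the complex I genes ND2 7.53 and ND4 6.11 times lower (camera adjusted p = 0.299 with an estimated correlation). Of 14 measured mineral and endocrine genes, 8 fell and 3 rose, with klotho Kl at -3.64 ± 0.30 and the angiotensin-converting enzyme Ace at -2.57 ± 0.09, while under library totals only 6 rose and 6 fell (camera adjusted p = 0.299 with an estimated correlation). Of 9 androgen-responsive kidney genes, 8 fell and 1 rose, with the steroid hydroxylase Cyp7b1 at -4.56 ± 0.12 and the polyamine enzyme Odc1 at -3.46 ± 0.13 (camera adjusted p = 0.126 with an estimated correlation).

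The other lists were not called. Of 23 purine handling genes, 8 rose and 11 fell, while under library totals only 18 rose and 3 fell. In it the urate transporter Slc22a12 stood at -4.79 ± 0.23, xanthine dehydrogenase Xdh at 1.64 ± 0.10, and Aprt, which converts adenine to AMP, at -0.42 ± 0.09 (edgeR adjusted p = 0.000951), with Aprt at 0.59 under library totals only. Of 13 NRF2 targets, 8 fell and 3 rose, the cystine transporter Slc7a11 by 5.56 ± 0.22, while under library totals only 6 rose and 3 fell. Of 15 unfolded protein and ATF4 response genes 4 rose and 3 fell, and of 14 immediate early genes 3 rose, while under library totals only 14 unfolded protein genes rose with 0 lower, and 6 immediate early genes rose. Of 7 urothelial genes 1 rose and 2 fell, and under library totals only 3 rose. Both measured adrenal cortex genes rose. No adipocyte gene of 7 passed by edgeR, DESeq2 or limma-voom, nor at an unadjusted p below 0.05. No sex-linked gene of 4 passed by edgeR, DESeq2 or limma-voom, with 1 at an unadjusted p below 0.05, while 1 rose under upper-quartile scaling and 3 under library totals only.

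Of the 34 lists, 24 were called by camera at the preset correlation and 4 with an estimated correlation, and adjusted over the list alone the counts were as given except for 5 podocyte genes lower, 1 B and plasma cell gene higher and 2 unfolded protein genes lower. Library totals only, a scaling added after seeing the data, gave 13197 higher and 1850 lower genes and moved the median log2 fold change over all genes to 1.05, against 0.17 with upper-quartile scaling and 0.04 with TMM, so directions here are relative to TMM.

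**Figure D2:**
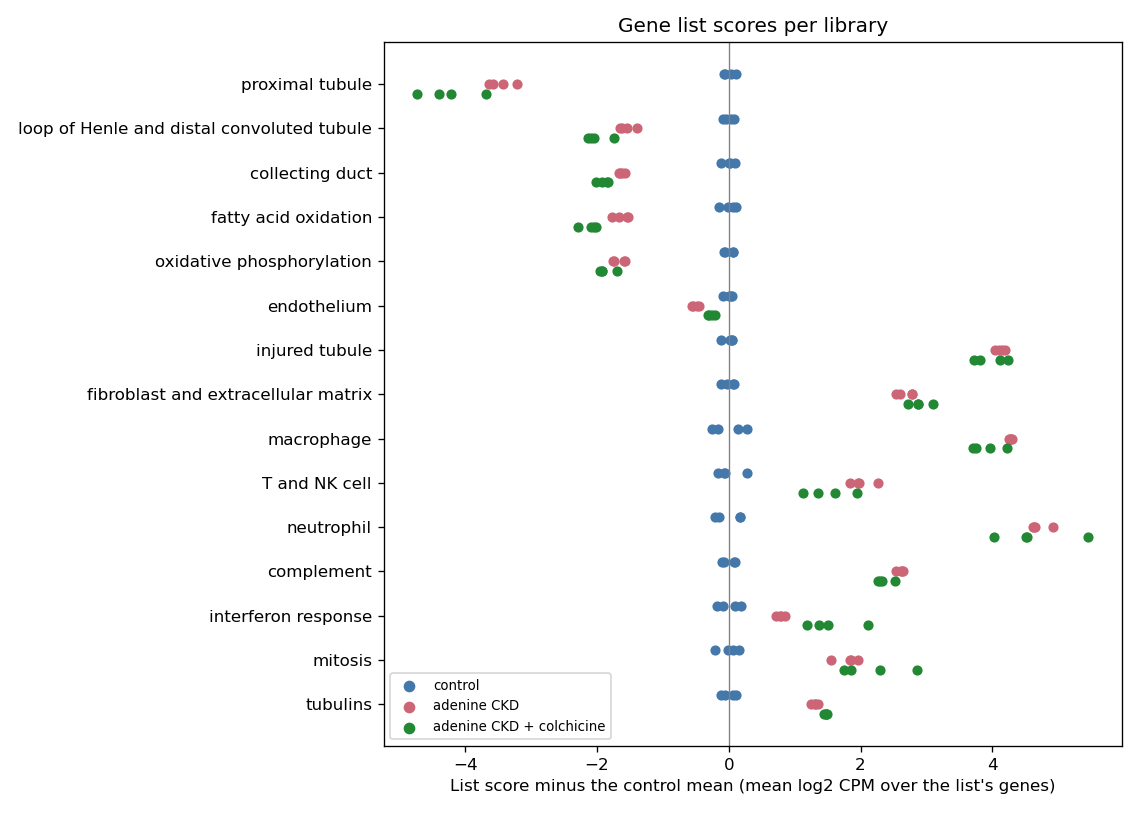
Each point is 1 library's score for a gene list, the mean log2 CPM over the list's genes minus the mean of the 4 control libraries, on the x axis, for 15 of the 34 lists. The proximal tubule score falls from a control mean of 9.69 to 6.23 in CKD and 5.43 with colchicine, and the macrophage score rises from 2.01 to 6.28 and 5.92.

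The comparison of colchicine with CKD asks what colchicine changed in adenine-fed kidneys. The labels give colchicine replicates 2, 3 and 4 more adenine (3, 4 and 5%) than the CKD libraries (2%), so for these 3 libraries the contrast does not separate colchicine from the labelled adenine. Only colchicine replicate 1 has the 2% label of the CKD libraries. It is 1 library without replication and lay apart from the other 3, so it cannot stand for colchicine at equal adenine. A fit with a slope on the labelled percentages, read at 2%, kept 25.9% of the 2682 genes called in the main fit. The interferon-stimulated gene Isg15, a ubiquitin-like modifier, rose from 8.72 ± 0.871 to 25.6 ± 5.24 CPM (SD, n = 4), and the collagen gene Col1a1 from 1235 ± 81.1 to 1770.3 ± 159 CPM. The water channel gene Aqp2 of the collecting duct fell from 35.9 ± 6.81 to 15.7 ± 1.64 CPM, and Ppara, a regulator of fatty acid oxidation, from 36.8 ± 4.09 to 15.6 ± 1.96 CPM. The complement gene C3 fell from 1380.3 ± 62.8 to 825 ± 172 CPM. By edgeR's quasi-likelihood test 1212 genes rose and 1470 fell, 15.0% of those tested, with a median absolute log2 fold change of 0.45 among them. By 2-fold or more, 139 rose and 145 fell, and 5881 genes had an unadjusted p below 0.05.

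The largest increases under the naming rule were in the histone gene H2ac23 (log2 3.10 ± 0.74), the metalloprotease Mmp10 (2.81 ± 0.77), the tubulin polymerization gene Tppp3 (2.11 ± 0.21), the acute phase gene Saa3 (1.77 ± 0.26), the autophagy gene Atg9b (1.69 ± 0.37), the GABA receptor gene Gabrb1 (1.62 ± 0.36), Apol9a (1.58 ± 0.37) and Isg15 (1.55 ± 0.16). H2ac23 passed at an edgeR adjusted p of 0.0187 but not without CKD replicate 3 (0.0636), and Mmp10 passed at 0.0390 but not without any 1 of the 4 CKD libraries (highest 0.113, without replicate 3). Without colchicine replicate 1 the log2 fold change of Mmp10 was 1.44, that of Mep1b -2.82 and that of Slco4c1 -2.63. Apol9a passed at 0.0132 and not without CKD replicate 3 (edgeR adjusted p = 0.0538). The largest decreases were in the glucuronosyltransferase Ugt1a10 (-2.71 ± 0.35), the protease inhibitor genes Serpina1d (-2.48 ± 0.13), Serpina1b (-2.07 ± 0.18) and Serpina1a (-1.93 ± 0.15), the brush border protease Mep1b (-2.06 ± 0.36), the transporter Slco4c1 (-1.83 ± 0.38), the lectin-like receptor Klrb1b (-1.76 ± 0.25) and the cytochrome P450 gene Cyp2a4 (-1.76 ± 0.16). The Serpina1 genes are close paralogs, and Ugt1a10, H2ac23, Apol9a, Klrb1b and Cyp2a4 have close relatives, so their shares of common reads are uncertain.

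**Figure D3:**
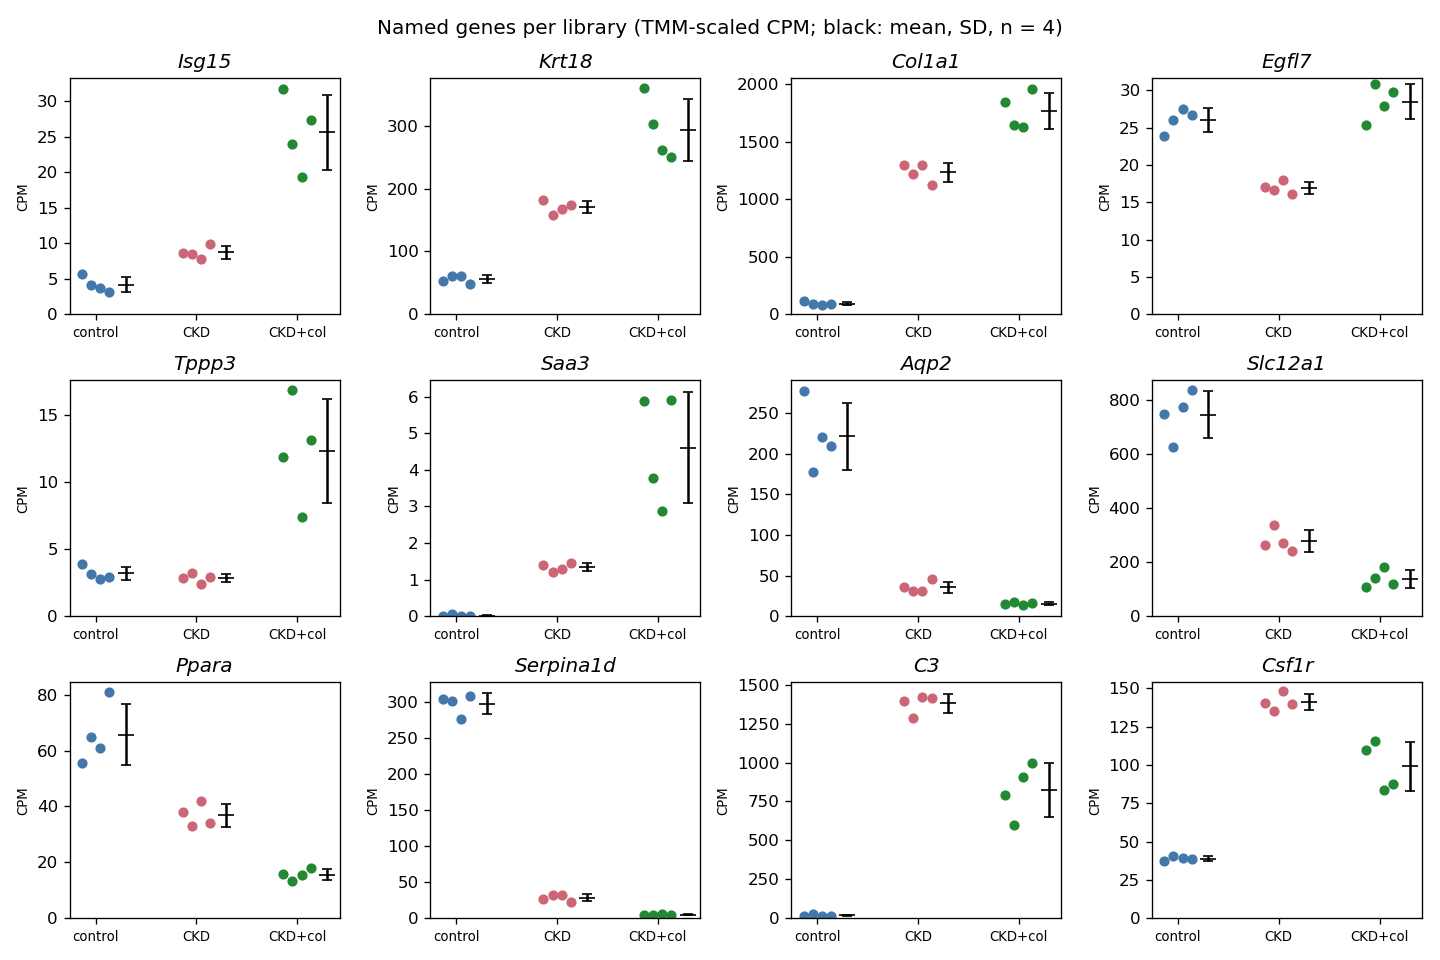
Each point is 1 library's TMM-scaled CPM on a linear y axis from 0, with the mean and SD of the 4 libraries in black, for 12 named genes. Isg15 averages 4.18 CPM in control, 8.72 in CKD and 25.6 with colchicine, and Ppara averages 65.6, 36.8 and 15.6 CPM.

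Camera at the preset correlation called lists of tubule segments and metabolism lower. Of 20 proximal tubule genes 9 fell, and 14 adjusted over the list alone, with the cytochrome P450 gene Cyp2e1 at -1.42 ± 0.29 and the fatty acid transporter Slc27a2 at -1.08 ± 0.24 (camera adjusted p = 0.314 with an estimated correlation). Of 15 genes of the loop of Henle and distal convoluted tubule 8 fell and 1 rose, 11 and 1 adjusted over the list alone, while under upper-quartile scaling 5 fell and 1 rose, with the salt transporter Slc12a1 at -1.02 ± 0.15, the potassium channel Kcnj1 at -0.73 ± 0.09 and Umod at -0.66 ± 0.15 (camera adjusted p = 0.203 with an estimated correlation). Of 15 collecting duct genes 3 fell, also adjusted over the list alone, with the water channels Aqp3 at -1.54 ± 0.13 and Aqp2 at -1.19 ± 0.15 (camera adjusted p = 0.314 with an estimated correlation). Of 20 fatty acid oxidation genes 13 fell, and 17 adjusted over the list alone and 10 under upper-quartile scaling, with Ppara at -1.24 ± 0.12 (camera adjusted p = 0.203 with an estimated correlation). Of 20 oxidative phosphorylation genes 9 fell, and 11 adjusted over the list alone, with the complex I gene Ndufs1 at -0.54 ± 0.10 and the complex II gene Sdha at -0.47 ± 0.09 (camera adjusted p = 0.423 with an estimated correlation). Of 14 mineral and endocrine genes 5 fell, and 6 fell and 1 rose adjusted over the list alone, with angiotensinogen Agt at -1.04 ± 0.13 and Ace at -0.55 ± 0.08 (camera adjusted p = 0.314 with an estimated correlation). Of 13 NRF2 targets 5 fell, and 6 adjusted over the list alone, with the quinone reductase Nqo1 at -0.90 ± 0.12 and Slc7a11 at -0.63 ± 0.14 (camera adjusted p = 0.203 with an estimated correlation). Of 9 androgen-responsive genes 3 fell, and 5 adjusted over the list alone (camera adjusted p = 0.363 with an estimated correlation). The erythrocyte score was 2.32 ± 0.573 in CKD and 1.34 ± 0.513 with colchicine (log2 CPM, SD, n = 4, exact permutation p = 0.0571). By edgeR and limma-voom 0 of 6 erythrocyte genes passed, while DESeq2 called 2 and 4 had an unadjusted p below 0.05 in edgeR (camera adjusted p = 0.448 with an estimated correlation).

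Camera at the preset correlation called the interferon, endothelial, matrix and mitosis lists higher. Of 15 interferon response genes 11 rose, and 12 adjusted over the list alone, with Ifit3, an inhibitor of viral RNA translation, at 0.92 ± 0.15 (camera adjusted p = 0.314 with an estimated correlation). Of 12 endothelial genes 4 rose, and 7 rose and 1 fell adjusted over the list alone, with the angiogenic factor Egfl7 at 0.75 ± 0.08 and the receptor Tie1 at 0.41 ± 0.07 (camera adjusted p = 0.203 with an estimated correlation). Of 20 fibroblast and matrix genes 11 rose, also adjusted over the list alone, with Col1a1 at 0.52 ± 0.10, osteonectin Sparc at 0.42 ± 0.08 and Acta2 at 0.39 ± 0.11, while Fn1 stood at -0.02 ± 0.15 without passing (camera adjusted p = 0.363 with an estimated correlation). Of 20 mitosis genes 4 rose, also adjusted over the list alone, with the cyclin-degrading enzyme Ube2c at 0.77 ± 0.21 and survivin Birc5 at 0.75 ± 0.15, and Mki67, which did not pass, at 0.39 ± 0.20 (camera adjusted p = 0.562 with an estimated correlation). Acta2 did not pass without colchicine replicate 4 (edgeR adjusted p = 0.0869) and in 4 other leave-outs, and Ube2c did not pass without CKD replicate 1 (0.0718) and in 3 others.

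Macrophage, T and NK cell, cytokine and complement lists were called lower by camera at the preset correlation. Of 16 macrophage genes 6 fell, also adjusted over the list alone, with Ms4a7 at -0.63 ± 0.14 and the growth factor receptor Csf1r at -0.51 ± 0.09 (camera adjusted p = 0.427 with an estimated correlation). Of 12 measured T and NK cell genes 3 fell, and 7 adjusted over the list alone, with Il7r at -0.89 ± 0.14 and Cd4 at -0.75 ± 0.16 (camera adjusted p = 0.358 with an estimated correlation). Of 22 cytokine and chemokine genes 5 fell, and 8 fell and 1 rose adjusted over the list alone, while under upper-quartile scaling 2 fell and 1 rose, with the chemokines Ccl3 at -0.87 ± 0.23 and Cxcl16 at -0.27 ± 0.07 (camera adjusted p = 0.358 with an estimated correlation). Ccl3 and Cxcl16 did not pass without colchicine replicate 2 (edgeR adjusted p = 0.0686 and 0.0678), and in 2 and 3 other leave-outs. Of 13 complement genes 4 fell, also adjusted over the list alone, with C3 at -0.74 ± 0.15 (camera adjusted p = 0.314 with an estimated correlation). The adipocyte score, a sign of attached fat, ranged widely within both groups, at 1.82 ± 2.76 in CKD and 3.43 ± 1.61 with colchicine (log2 CPM, SD, n = 4).

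The remaining lists were not called. Of 20 injured tubule genes 6 rose and 5 fell, and 8 and 6 adjusted over the list alone, with the keratin Krt18 at 0.78 ± 0.11, the annexin Anxa2 at 0.47 ± 0.07 and Spp1 at -0.59 ± 0.15. The median log2 fold change of this list was 0.04 and its mean -0.10, while camera's direction was up. Spp1 did not pass without CKD replicate 3 (edgeR adjusted p = 0.0757), nor without colchicine replicate 3. Of 15 inflammasome and interleukin 1 genes 1 rose and 2 fell, and 1 and 3 adjusted over the list alone, with the sensor Nlrc4 at -0.93 ± 0.17 and Il1rn at -0.54 ± 0.11. Nlrp3 (-0.12 ± 0.20), Casp1 (-0.27 ± 0.12) and Il1b (-0.49 ± 0.23) did not pass, with edgeR adjusted p of 0.683, 0.137 and 0.164. Havcr1 (-0.58 ± 0.39), Lcn2 (0.36 ± 0.16), Slc34a1 (-0.37 ± 0.17), Kl (-0.63 ± 0.27), Tgfb1 (0.04 ± 0.07), Ccl2 (0.08 ± 0.19) and S100a8 (-0.53 ± 0.19) did not pass either. Without colchicine replicate 1, Havcr1 passed at -1.13 and S100a8 at -0.72 (edgeR adjusted p = 0.0166 and 0.00360). Slc34a1 passed at -0.63 without colchicine replicate 4 (edgeR adjusted p = 0.00206) and Il1b at -0.70 without CKD replicate 1 (0.0226). Of 12 tubulin genes, whose products colchicine binds, 0 passed by edgeR and DESeq2, 1 passed by limma-voom, 2 rose under upper-quartile scaling in edgeR, 2 rose without colchicine replicate 1 and 2 had an unadjusted p below 0.05, with Tuba1a at 0.09 ± 0.09, Tubb2a at -0.06 ± 0.12 and Tubb5 at 0.15 ± 0.07. The tubulin score was 5.33 ± 0.0429 in CKD and 5.49 ± 0.0199 with colchicine (log2 CPM, SD, n = 4, exact permutation p = 0.0286, adjusted over the lists 0.0971). Of 15 p53 targets 4 rose and 1 fell, and 5 and 2 adjusted over the list alone. Cdkn1a stood at 0.55 ± 0.16 and did not pass without CKD replicate 3 (edgeR adjusted p = 0.0880) and in 4 other leave-outs, and stood at 0.31 without colchicine replicate 1. Of 23 purine handling genes 1 rose and 2 fell, and 2 and 6 adjusted over the list alone, with Aprt at 0.45 ± 0.09, adenosine kinase Adk at -0.55 ± 0.11 and Xdh, which did not pass, at -0.01 ± 0.09. Of 12 podocyte genes 3 rose (4 adjusted over the list alone), of 18 TGF-beta signalling genes 3 rose, of 6 B and plasma cell genes 1 fell, of 4 sex-linked genes 1 fell, and of 18 DNA replication genes 1 fell (0 adjusted over the list alone). Of 10 neutrophil genes 1 rose and 1 fell (1 and 2 adjusted over the list alone), with a median log2 fold change of -0.30 and a mean of 0.04, while camera's direction was down. Of 15 unfolded protein and ATF4 response genes 2 rose and 1 fell (3 and 3 adjusted over the list alone). By edgeR, DESeq2 and limma-voom 0 of 14 immediate early genes, 9 mitochondrially encoded transcripts, 7 adipocyte genes, 2 adrenal cortex genes and 7 urothelial genes passed. At an unadjusted p below 0.05 there was 1 mitochondrially encoded transcript and 0 of the others. The immediate early genes had a median log2 fold change of -0.01 and a mean of 0.07 with camera's direction down, and a median of 0.05 under upper-quartile scaling and 0.02 under library totals only.

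Camera called 17 of the 34 lists at the preset correlation. With an estimated correlation camera called 0, with 4 at an unadjusted p below 0.05, while fry called 12 and the exact permutation test of the scores 0, with 10 unadjusted. Those 10 stood at the smallest possible exact permutation p of 0.0286, which adjusted to 0.0971. The adjusted value depends on how many lists reach that p, so this 0 does not count against the 10 lists. Without colchicine replicate 1, whose profile lay apart from the other 3, 2882 genes rose and 3519 fell. Camera then no longer called the collecting duct (adjusted p = 0.154), matrix (0.0534), chemokine (0.0560), complement (0.0534), mitosis (0.231), mineral (0.0571) and erythrocyte (0.150) lists, and called the podocyte and purine lists (camera adjusted p = 0.0422 and 0.0422). The median log2 fold changes of the lists no longer called went, in that order, from -0.16 to -0.18, 0.34 to 0.31, -0.25 to -0.24, -0.22 to -0.24, 0.43 to 0.14, -0.35 to -0.40 and -1.11 to -0.90. Counts of higher and lower genes were 580 and 846 without CKD replicate 1, 662 and 899 without 2, 419 and 573 without 3, and 640 and 878 without 4. They were 489 and 707 without colchicine replicate 2, 629 and 756 without 3, and 724 and 1252 without 4. The share of called genes that rose was 45.2% under TMM, 37.5% under DESeq2 size factors in edgeR, 59.8% under upper-quartile scaling and 54.5% under library totals only.

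Both comparisons share the CKD libraries, and the overlap of their calls was counted. Colchicine replicates 2, 3 and 4 are labelled with more adenine (3, 4 and 5%) than CKD (2%). Changes given here as with colchicine therefore include any effect of that adenine. Of the genes called in both, 1480 changed in the same direction with adenine and with colchicine, 564 up and 916 down, and 680 changed in opposite directions, 341 up then down and 339 down then up. C3, Csf1r, Il7r and Spp1 rose with adenine and fell with colchicine, and Egfl7, Tie1 and Aprt fell and then rose. Aqp2, Slc12a1 and Ppara fell in both, and Col1a1, Krt18 and Isg15 rose in both. Independent lists of these lengths would give 905 opposite and 903.2 same-direction genes. In 20 simulations with the colchicine group unchanged from CKD, the mean was 0.200 opposite and 0.05 same-direction genes. Hardly any gene is called in both comparisons there, so these counts are no measure for the 680. The correlation of the fold changes across genes was 0.07, against a mean of -0.09 in these simulations, and genes are not independent replicates. With the CKD libraries split 2 and 2 between the comparisons, 59 to 161 genes were opposite and 145 to 581 in the same direction, and the correlations were 0.04 to 0.12. The opposite calls without CKD replicates 1, 2, 3 and 4 in turn numbered 301, 336, 233 and 392.

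**Figure D4:**
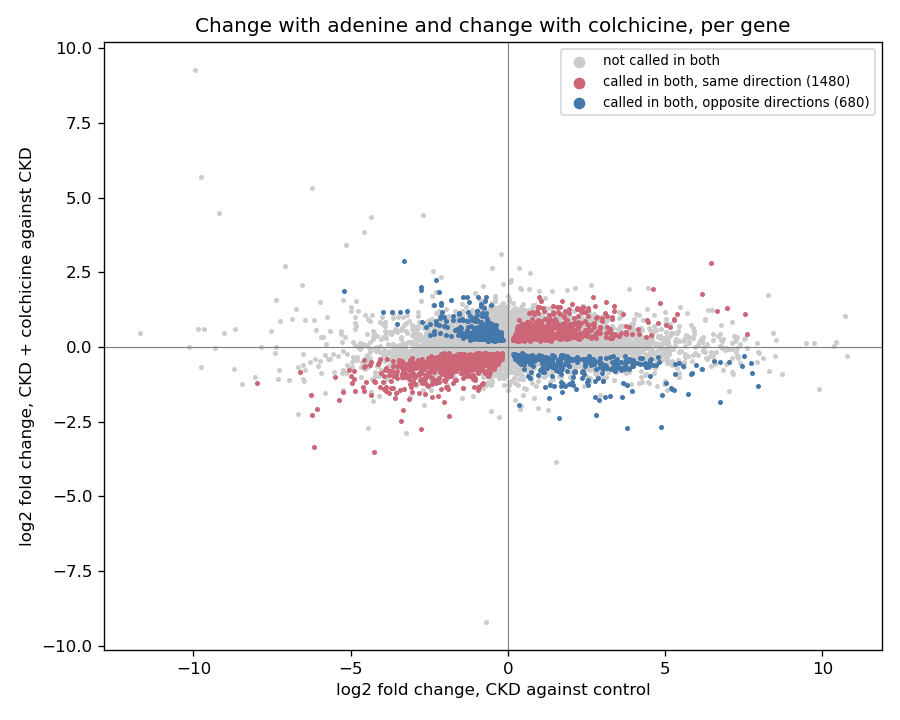
Each point is 1 gene, with its log2 fold change for CKD against control on the x axis and for colchicine against CKD on the y axis. The 1480 genes called in both in the same direction are red, the 680 called in opposite directions are blue, and the rest are grey.

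The labels give the colchicine libraries different adenine percentages, and a slope on them was tested within that group. By edgeR 226 genes followed the labelled percentages, 118 rising and 108 falling, and 3526 had an unadjusted p below 0.05. Of the 12 orders of the labels, another called 931 genes.

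The comparison of colchicine with control asks what remained different from control under colchicine. The injury, matrix and immune genes Lcn2, Havcr1, Fn1, Col1a1, Ccl2 and Spp1 stayed higher than in control, with Lcn2 186-fold, Havcr1 81.0-fold, Fn1 19.7-fold, Col1a1 19.3-fold, Ccl2 18.5-fold and Spp1 16.4-fold higher. Slc34a1 and Kl stayed lower, 20.8 and 19.3 times. Umod, which had not passed in CKD against control, was 1.87 times lower, and stood at 0.14 (log2) under library totals only. By edgeR's quasi-likelihood test 6612 genes were higher and 5964 lower, and 3770 and 2814 by 2-fold or more. Sprr2f was at least 325-fold and Il36a at least 139-fold higher against the floor, Mmp7 rose 1375-fold and the arginase gene Arg1 rose by 10.02 ± 1.14 on the log2 scale. Slco1a1 was 2423 times, Slc22a7 1389 times and Slc22a30 814 times lower, and the sperm mitochondrial gene Smcp, with 1 count left, was lower by a ratio of 1217 (interval 218 to 48174). Without control replicate 1 the log2 fold change was 11.26 for Mmp7, against 10.42, and 10.87 for Arg1. Without colchicine replicate 1 it was 9.11 for Arg1, -12.16 for Slco1a1, against -11.24, and -10.28 for Slc22a30, against -9.67, and no Smcp count was left.

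The inflammation genes Il1b (3.78 ± 0.32), Nlrp3 (3.22 ± 0.26), Casp1 (2.14 ± 0.14) and S100a8 (4.56 ± 0.29) were higher than in control, as were Tgfb1 (2.03 ± 0.07), Acta2 (1.47 ± 0.11), Cdkn1a (3.40 ± 0.19), Mki67 (2.51 ± 0.22) and Xdh (1.63 ± 0.10). The tubulin genes Tuba1a (2.32 ± 0.10), Tubb5 (2.29 ± 0.08) and Tubb2a (1.17 ± 0.12) were higher as well. Aprt did not pass, at 0.02 ± 0.09 (edgeR adjusted p = 0.833). All 20 proximal tubule genes fell (camera adjusted p = 0.136 with an estimated correlation), and 19 of 20 injured tubule genes rose (camera adjusted p = 0.0635 with an estimated correlation). All 20 matrix genes (camera adjusted p = 0.111 with an estimated correlation) and all 16 macrophage genes rose (camera adjusted p = 0.116 with an estimated correlation). Of 15 interferon response genes 14 rose (camera adjusted p = 0.356 with an estimated correlation). Of 6 B and plasma cell genes 1 rose and 2 fell, without a call of the list, and the list's median was 0.06 while camera's direction was down. Of 12 endothelial genes 5 fell and 1 rose, without a call of the list, while 4 fell and 4 rose under upper-quartile scaling and 10 rose under library totals only. The counts of these 7 lists were the same adjusted over the list alone.

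Camera called 24 lists at the preset correlation. With an estimated correlation camera called 0, with 12 at an unadjusted p below 0.05, while fry called 28 and the exact permutation test of the scores 28. The share of called genes that rose was 52.6% under TMM, 51.3% under DESeq2 size factors in edgeR, 62.7% under upper-quartile scaling and 87.6% under library totals only, with median log2 fold changes over all genes of 0.10, 0.08, 0.30 and 1.14.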

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

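The tests of colchicine replicate 1 and of the lists moving in both directions were chosen after the results were seen, and the counts of other splits were planned.

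For the number of genes called, the splits argue against chance assignment of the libraries in all 3 comparisons. With 35 splits the share cannot fall below 0.0286, so they do not exclude it. Of 35 splits of the 8 libraries compared, only 1, the real one, reached 12028 genes for CKD against control, and the highest other split called 0. For colchicine against CKD, 1 split reached 2682 genes, and the highest other called 590 when CKD replicate 4 and colchicine replicate 1 changed places. For colchicine against control, 1 split reached 12576 genes and the highest other called 1. The 680 opposite calls were reached by 1 split of 35, with 246 in the highest other. An opposite call needs a gene called for colchicine against CKD, and the other splits called few or none. So this count adds nothing to the number of genes called and does not test the opposition. For the number of lists called, the splits do not decide for CKD against control and colchicine against control, because the count saturates. Splits that exchange 1 library between the groups called 23 to 26 and 11 to 25 lists, and those that exchange 2 called 0 to 5 and 0 to 11. For colchicine against CKD, with 4 to 18 and 5 to 16 in such splits, chance cannot be excluded for the number of lists. At least as many lists as the real 24, 17 and 24 were called in 11, 6 and 9 of 35 splits, for CKD against control, colchicine against CKD and colchicine against control. The highest other splits called 26, 18 and 25 lists. For the slope on the labelled adenine percentages, the 12 orders are too few for a share under 0.05. The labelled order called 226 genes, 4 of the 12 orders called as many, and the highest other called 931.

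Colchicine replicate 1 lay apart from the other 3 colchicine libraries. Its correlations with replicates 2, 3 and 4 (log2 CPM) were 0.977, 0.968 and 0.974, against 0.984 to 0.986 among those 3. On the second principal component it lay at -22.1, among the CKD libraries at -30.9 to -7.16. Replicates 2, 3 and 4 lay at 30.8, 50.4 and 28.1. By edgeR it also differed from the other 3 in more genes than each of those from its own other 3. The reference sets of those 3 held replicate 1, which can widen their spread and lower their counts. Whether replicate 1 is a mislabelled CKD library cannot be decided here. It differed from each set of 3 CKD libraries in 482 to 600 genes, and a CKD library from the other 3 in at most 11. The lone library was assumed to vary like the others. The groups share one spread, and replicate 1 stays in the colchicine group only when a CKD library is tested. That can widen the spread and lower the counts of the CKD libraries. Without replicate 1, calls for colchicine against CKD went from 1212 higher and 1470 lower to 2882 and 3519. The test of gene counts replaced an undecided one of the position of replicate 1 between the groups (0.280 to 0.345, CKD libraries -0.00155 to 0.302, where 0 is CKD and 1 colchicine). The tables argue against depth, since the replicate 1 total of 28.6 M (1000000 counts) lay within the 23.9 to 38.3 M of its group. A linear effect of the labelled adenine percentage is not decided. Replicate 4 (5%), labelled as far from the mean of its other 3 as replicate 1 (2%), differed from them in 13 genes. Those 3 included replicate 1, which can widen the spread and lower this count. That test replaced the count of label orders. A weaker response to colchicine in all lists may be open. Of 12 lists called without this library, it lay nearest to CKD among the colchicine libraries in 5. It lay within the CKD range for the podocyte, T and NK cell, purine and androgen lists. For the others of the 12 it lay outside that range, on the side of the other colchicine libraries. It lay farther from CKD than each of the other 3, by more than their SD, in 1, where 2 were asked for. That list was the interferon response (6.02 against 5.09 to 5.42, with CKD at 4.62 to 4.76, log2 CPM). This test replaced one on lists called with the library. A step between the label of 2% and the higher labels cannot be told apart from a difference of this 1 mouse, because the 3208 genes rest on 1 library.

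In colchicine against CKD, camera called lists in both directions, with 4 of 12 endothelial genes higher and 6 of 16 macrophage and 9 of 20 proximal tubule genes lower, but with an estimated correlation the camera adjusted p were 0.203, 0.427 and 0.314. A lower share of proximal tubule cells would raise the other cell types alike, but the endothelial minus macrophage score shifted by 0.596 (log2, exact permutation p = 0.0286), from -0.701 ± 0.0612 to -0.106 ± 0.192 (SD, n = 4). The scaling of the libraries cancels in a difference of scores, and the endothelial minus proximal tubule score rose by 1.03 (exact permutation p = 0.0286). Changes of several cell types at once, fewer macrophages or another state of the cells may be open, and bulk counts do not separate them. The higher labelled adenine of colchicine replicates 2, 3 and 4 may contribute, while replicate 1, labelled 2% as CKD is, stood at -0.144 and 0.362 for these 2 differences, outside the CKD ranges of -0.747 to -0.618 and -0.866 to -0.484.

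A separate search used Dixon's test, at its 95% critical value, for a library far from the other 3 of its group. It picked out 34 of 525 groups of 4 values, and 8 of the 34 lay in colchicine replicate 1. The 5% rate of the test would give 26.2, but that rate holds for independent normal values. Genes of a list and its score are related, and a gene at 0 in the other 3 libraries is always picked out. So 26.2 is no firm measure of chance here. Values follow as that of the library against those of the other 3. In colchicine replicate 1 these were, in CPM, Trem1 (7.52 against 2.37 to 3.13), Cyp2d12 (0.244 against 0.0201 to 0.0348), Bmp7 (17.0 against 16.0 to 16.1), Nlrp3 (6.74 against 4.07 to 4.52), Mmp10 (7.39 against 0.806 to 1.29), Mep1b (2.04 against 0.400 to 0.645), Slco4c1 (1.82 against 0.363 to 0.557) and Smcp (0.0272 against 0). In colchicine replicate 2 it was Umod (1032 against 607 to 674 CPM), and in replicate 3 the sex-linked list score (4.28 against 4.91 to 5.03 log2 CPM). In colchicine replicate 4 these were Pvalb (0.209 against 0 to 0.0272 CPM), Aqp3 (5.64 against 3.67 to 3.91), Cxcl16 (148 against 133 to 135), Fgg (194 against 57.0 to 77.5) and the oxidative phosphorylation score (6.86 against 6.60 to 6.64 log2 CPM). In the CKD group these were Cd74 in replicate 1 (1014 against 1206 to 1228 CPM), Ccl3 (18.5 against 13.7 to 14.3 CPM), Irf8 (41.6 against 34.6 to 35.5 CPM) and the neutrophil score (3.87 against 3.57 to 3.61 log2 CPM) in replicate 2, and Spp1 (16982 against 14299.7 to 14656 CPM) and Kl (62.1 against 48.1 to 49.4 CPM) in replicate 3. In control replicate 1 these were ND4 (100404 against 80716 to 83990 CPM), Lcn2 (7.93 against 3.90 to 4.53), Col1a1 (113 against 83.1 to 86.1), Cyp2e1 (1863 against 1969.7 to 1973) and the B and plasma cell score (-0.0871 against 0.355 to 0.439 log2 CPM). In control replicate 2 these were Clca3b (0.0509 against 0 CPM), C3 (25.1 against 16.5 to 18.0) and Saa3 (0.0509 against 0). In control replicate 3 these were Ccl20 (0.0685 against 0 CPM), Cyp2a4 (459 against 499 to 503) and Efhb (0.137 against 0.0509 to 0.0583), and in control replicate 4 Kdr (74.6 against 66.7 to 67.6 CPM) and Tubb2b (11.9 against 10.3 to 10.4).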

How the results depend on the processing

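Scaling by library totals only, leaving out mitochondrially encoded transcripts and camera without colchicine replicate 1 were chosen after the data were seen, and the other alternatives were planned.

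Among the genes named, the alternatives fixed before the data left direction and side of the threshold the same in 1151 results for CKD against control, 1502 for colchicine against CKD and 533 for colchicine against control. Results lost the threshold in 0, 120 and 0 cases, gained it in 1, 12 and 0, and reversed in 0, 22 and 7. For the gene lists 107, 95 and 102 results stayed the same, 20, 39 and 24 lost the threshold, and 9, 0 and 8 gained it. Leaving out any 1 library kept the calls of 71 of 71, 59 of 73 and 29 of 29 called genes. Many of these genes were named for a large change or a small p. Of all genes called for colchicine against CKD, 36.8% were kept without CKD replicate 3 and 43.8% without colchicine replicate 2. The other leave-outs kept 49.4% (without colchicine replicate 3) to 98.7% (without colchicine replicate 1).

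The 2-fold threshold gave 3329 higher and 2739 lower genes for CKD against control, 139 and 145 for colchicine against CKD, and 3770 and 2814 for colchicine against control, by its construction. Library totals only gave 13197 and 1850 for CKD against control and 13762 and 1953 for colchicine against control, since they leave out the composition factors. For colchicine against CKD, the replicate block gave 694 higher genes, the slope on adenine 392 higher and 616 lower, and colchicine replicate 1 alone, assumed to vary like the other groups, 532 and 660. DESeq2 gave 2303 lower genes. Leaving out 1 library gave 419 (without CKD replicate 3) to 2882 (without colchicine replicate 1) higher and 573 to 3519 lower genes, with the same libraries at the ends. The opposite calls numbered 412 with the block and 233 (without CKD replicate 3) to 392 (without CKD replicate 4), and limma-voom called 352 genes by the slope. An estimated correlation left camera 4 lists for CKD against control, 0 for colchicine against CKD and 0 for colchicine against control, with 10, 4 and 12 at an unadjusted p below 0.05. The exact permutation test of scores called 0 for colchicine against CKD (10 unadjusted, all at its smallest possible p of 0.0286), while fry called 12.

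Reversed log2 fold changes were those of Umod (0.7647) and Aprt (0.5891) for CKD against control under library totals only. For colchicine against CKD, with colchicine replicate 1 alone they were those of Havcr1 (0.3668), Fn1 (0.3552), Nlrp3 (0.3227), Batf3 (-0.1509), Zbtb46 (-0.1375) and Xdh (0.0945), and with the slope those of Fn1 (0.2421), Nlrp3 (0.1941) and Xdh (0.1582). With upper-quartile scaling they were those of Fn1 (0.0329), Tubb2a (0.0059) and Xdh (0.046), with library totals only those of Fn1 (0.0045) and Xdh (0.0135), and with limma-voom that of Ccl2 (-0.0035). Over the leave-outs Fn1 ranged from -0.1784 to 0.0877 (reversed without CKD replicate 1 or 3 or colchicine replicate 3 or 4), Xdh from -0.0578 to 0.0482 (reversed without CKD replicate 1 or colchicine replicate 4), Tgfb1 from -0.0047 to 0.0818 (reversed without colchicine replicate 2), Ccl2 from -0.1347 to 0.2679 and Tubb2a from -0.1068 to 0.0001 (both reversed without colchicine replicate 1). For colchicine against control, Umod reversed under library totals only (0.139) and Aprt with DESeq2 (-0.0004), RLE (-0.0003), the slope (-0.1151), colchicine replicate 1 alone (-0.2243), and its leave-outs ranged from -0.0552 to 0.1006 (reversed without control replicate 4 or colchicine replicate 2 or 4). In colchicine against CKD the injured tubule (exact permutation adjusted p = 0.432) and immediate early lists (0.971) reversed under the exact permutation test, and in colchicine against control the B and plasma cell list did under fry (adjusted p = 0.777) and the exact permutation test (0.707). For these reversals and for the counts without a stated reason, the cause was not tested.

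Correlations of library pairs by replicate number across groups ranged from -0.279 to 0.189, so the numbers do not pair the libraries. A pattern in the mitochondrially encoded share was weighed first and dropped without a verdict. Leaving these transcripts out kept 99.2% of the calls for CKD against control, but TMM trims genes of extreme ratio or abundance, so this says little about their effect. The change of pseudocount applies to normalized values and was not run. Depth and spread limit small changes, since 41.5% of simulated 1.5-fold changes were recovered for colchicine against CKD.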

Other observations

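The 7 lists, the genes named from them and the tests of the clock pattern were chosen after the results were seen, so they are hypotheses and not independent evidence.

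Antigen-presenting cells sample tissue antigens and show them to T cells through MHC class II. Of 19 genes of dendritic cells and MHC class II, 17 rose in CKD against control and 16 fell with colchicine against CKD, including H2-Aa (-1.26 ± 0.19, log2, SE), H2-Eb1 (-1.17 ± 0.18) and the invariant chain Cd74 (-1.03 ± 0.15). With colchicine against CKD, 12 fell under upper-quartile scaling and 14 under library totals only. The growth factor receptor Flt3 (-1.67 ± 0.23) and the markers of cross-presenting dendritic cells Xcr1 (-1.71 ± 0.35) and Clec9a (-1.33 ± 0.31) fell too, while the factors Batf3 (0.27 ± 0.20), Zbtb46 (0.12 ± 0.11) and Irf8 (-0.21 ± 0.10) of these cells did not pass (edgeR adjusted p = 0.358, 0.429 and 0.150). The list score fell from 3.99 ± 0.136 in CKD to 3.05 ± 0.292 with colchicine (log2 CPM, SD, n = 4, exact permutation p = 0.0286). Of 12 genes of regulatory T cells and checkpoint receptors, 12 rose in CKD and 4 fell with colchicine, or 6 without colchicine replicate 1, including the regulatory T cell factor Foxp3 (-1.20 ± 0.31) and the checkpoint receptor Btla (-1.18 ± 0.26). Foxp3 did not pass without CKD replicate 3 (edgeR adjusted p = 0.0726) and in 4 other leave-outs.

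Motile cilia move fluid, and their genes follow the factor Foxj1. Of 24 motile cilium genes, 12 rose with colchicine against CKD, including Foxj1 (0.75 ± 0.17), the dynein regulator Drc1 (1.31 ± 0.27) and Efhb (1.21 ± 0.25), and the score rose from -0.0811 ± 0.0627 to 0.794 ± 0.172 (exact permutation p = 0.0286). In CKD against control 10 rose and 3 fell. Tppp3, among the largest increases, was known before the list was built.

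Fibrinogen is a clotting protein made by the liver and by injured tubules. All 3 fibrinogen genes rose in CKD against control and fell with colchicine, with Fga at -1.48 ± 0.28, Fgb at -1.35 ± 0.38 and Fgg at -1.40 ± 0.35, and 2 fell without colchicine replicate 1. Fgb and Fgg did not pass without colchicine replicate 3 (edgeR adjusted p = 0.113 and 0.0810) and in 5 and 4 other leave-outs. Of 12 plasma protein genes typical of liver, 11 fell with colchicine, a list that holds the fibrinogen genes and the Serpina1 genes. Without colchicine replicate 1, 10 fell and 1 rose. In CKD against control 5 genes of this list rose and 5 fell. The fibrinogen genes are also among the injured tubule genes.

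The circadian clock runs in opposite phases, with Bmal1 and Npas2 high when Dbp, Hlf, Tef and Ciart are low. In colchicine against CKD, Bmal1 (0.62 ± 0.16) and Npas2 (0.98 ± 0.17) rose, while Dbp (-0.96 ± 0.11), Hlf (-1.33 ± 0.14), Tef (-0.72 ± 0.11) and Ciart (-1.10 ± 0.31) fell, as did 6 of 10 genes of the opposite phase, or 8 without colchicine replicate 1. Bmal1 and Ciart did not pass without colchicine replicate 2 (edgeR adjusted p = 0.0783 and 0.0984) and in 5 and 6 other leave-outs. The scaling of the libraries cancels in the difference of the 2 phase scores, and that difference rose by 0.870 (log2, exact permutation p = 0.0286) after rising by 0.994 in CKD against control. Kidneys collected at another time of day may be a cause that cannot be told apart from an effect of colchicine on the clock, since collection times are not given and, of 6 genes of the Bmal1 phase, 2 rose (with 2 falling without colchicine replicate 1), with an exact permutation p of 0.486 for their score. A first wording of this test, which asked only for the fall in 1 phase beside Bmal1 and Npas2, was met and was tightened after its result was seen to ask that both scores move.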
